A study of Rattus norvegicus with 4 samples.

How the data were processed

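Chromatin immunoprecipitation with sequencing (ChIP-seq) of the transcription factor JUN was carried out on the distal stump of transected rat sciatic nerve, collected 8 days after the cut, in male Sprague Dawley rats. The labels list 4 libraries, 2 of JUN ChIP DNA and 2 of input DNA, and describe the ChIP libraries as biological replicates prepared from freshly dissected nerve by an MNase-based protocol with 4 µg of JUN antibody. The purpose of an input library is to measure the background of sheared or digested chromatin without antibody.

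The deposited table is 1 peak list for the whole series. It has 3 columns without a header, which give the chromosome, start and end of each interval in base pairs (unit: other, genomic positions as the authors deposited them). Per the submitters' processing notes, the genome build was rn5 and the tools were CASAVA 1.8.2, Bowtie2, MACS2, bedtools and deepTools. The role, order and settings of these tools, the peak threshold, and whether replicates were pooled, intersected or called separately are not given in the sources used here. The list carries no height, fold enrichment, p-value, gene name or value per library. Sequencing depth was therefore unknown, no error between replicates could be given, and ChIP and input could not be compared by a test. Every interval had the same width of 300 bp, so the width of a peak carries no information on the enriched region. Starts were taken as 0-based, as in BED files, because end minus start was exactly 300, and positions are printed 1-based.

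The reference table at hand holds genes of the assembly GRCr8. The last peak lay beyond the last gene of that table on 12 of 21 chromosomes, so the positions of the 2 builds are not interchangeable. The table was not used to name genes, and no genome sequence of rn5 was used here. The tests planned before the data were examined that need gene positions, sequence or a peak score were thus not run: distance to transcription start sites, the AP-1 and other binding motifs, genes linked to peaks, and the enrichment of fixed gene lists, including markers of Schwann cells, macrophages, fibroblasts and other nerve cell types. The rule that was to name genes could not be applied. In its place, regions are named by the number of peaks they hold (the 10 largest groups), a rule chosen after the peak list was seen.

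Peaks were counted per chromosome, and the density was taken over the length from the chromosome's first base to its last peak, since chromosome lengths of rn5 were not used here. The planned fit of peak counts to chromosome lengths was not run for that reason. The mean density per chromosome was computed over whole 5 Mb windows with a 95% bootstrap interval from 10000 draws of windows. X and autosomal windows were compared with a 2-sided permutation test of 100000 window reassignments, and differences among the autosomes with a permutation test of the variance between chromosomes. Windows are not biological replicates, so these intervals and p-values describe this list only and are too narrow as a measure of error between animals. Neighbouring windows are also correlated, so the intervals may be too narrow and the p-values too small for this list as well.

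Groups of peaks were formed by joining neighbours with gaps of at most 12.5 kb, the stitching distance commonly used for enhancer clusters. The observed groups were compared with 1000 random placements in which each peak kept its chromosome and its 1 Mb window, and no 2 peaks in a window came closer than the smallest gap seen in the list, 73 bp. The 2-sided p-value of these placements cannot fall below 0.002. The random placements were tested on simulated data with 99 placements per set. Of 40 sets of 17014 peaks placed at random by the same rule, 3 gave p under 0.05. A random set of 17014 peaks to which 200 planted groups of 8 peaks were added gave a 2-sided permutation p = 0.02. That is the smallest p that 99 placements can give. The joining rule, tested apart, returned all 200 planted groups. Their gaps were all set below 12.5 kb, so this recovery was certain and checks the code only. Alternatives were gaps of 5 and 25 kb, joining peaks closer than 500 bp or 1 kb, other placement windows, 50% of the peaks drawn at random and the list without X. The gaps of 5 and 25 kb and the 500 bp join for the number of peaks were set before the data were examined, and the others after. The random placements and the comparison of X with the autosomes were themselves chosen after the peak list was seen, in place of the tests that could not be run. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used.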

Results

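JUN, a subunit of the AP-1 transcription factor, is induced in Schwann cells after nerve injury and is required for their conversion to repair cells. To locate where JUN sits on the genome in injured nerve, JUN ChIP-seq was performed on the distal stump of the rat sciatic nerve 8 days after transection, with 2 ChIP libraries and 2 input libraries. The distal stump also contains macrophages, fibroblasts and endothelial cells, and the list does not separate the cell types. The series holds no uninjured nerve among the samples analysed here, so the data describe occupancy in injured nerve and not a change upon injury. The authors' peak list gave 17017 intervals of 300 bp, which together covered 5.11 Mb. Of these, 17014 lay on the 20 autosomes and X, and 3 lay on unlocalised contigs assigned to chromosomes 2, 7 and 15. No peak was listed on Y or on the mitochondrial genome. Whether the build used by the authors holds Y sequence was not checked here, so this does not show that JUN is absent from Y. All positions are given on rn5, and which gene, exon or intron each peak falls in was not analysed here.

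JUN peaks were found on all 20 autosomes and were scarce on X. The densest chromosomes were 12, 10 and 20. They held 638, 1291 and 548 peaks, at 11.9, 11.5 and 9.48 peaks per Mb. The sparsest autosomes were 4, with 958 peaks at 3.87 peaks per Mb, 11, with 392 peaks at 4.22 peaks per Mb, and 2, with 1207 peaks at 4.24 peaks per Mb. The place of chromosome 11 depended on its first 13.3 Mb, which held no peak. Over the length from first to last peak, it had 4.93 peaks per Mb, above chromosome 15 at 4.70. Chromosome 4 had the lowest autosomal value over this length too, 3.87 peaks per Mb. This check removes only peak-free ends, however, and chromosome 4 has an interior stretch of 67.4 Mb without a peak. Its rank as the sparsest autosome may rest on that stretch. Chromosome 1 held the most peaks, 2061, at 7.13 peaks per Mb. With the peak-free stretch of chromosome 4 counted, the highest and lowest autosomal densities differed 3.08-fold around a median of 6.08 peaks per Mb.

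Over 5 Mb windows, the mean density was 11.6 peaks per Mb on chromosome 10 (95% bootstrap interval 8.75 to 14.7, 22 windows) and 11.5 on chromosome 12 (8.70 to 14.6, 10 windows). The corresponding means were 3.84 on chromosome 4 (2.72 to 5.08, 49 windows) and 4.23 on chromosome 2 (3.24 to 5.29, 57 windows). The intervals of chromosomes 10 and 12 did not overlap those of chromosomes 2 and 4. These chromosomes were picked as extremes by the same density, so the lack of overlap is not a test. The windows of chromosome 4 include its 67.4 Mb stretch without a peak. Chromosome 20 had a wider interval, from 4.80 to 16.4 over 11 windows, which overlapped that of chromosome 4. The autosomes differed from one another by more than reassigned windows did (permutation test, p = 2e-05).

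**Figure D1:**
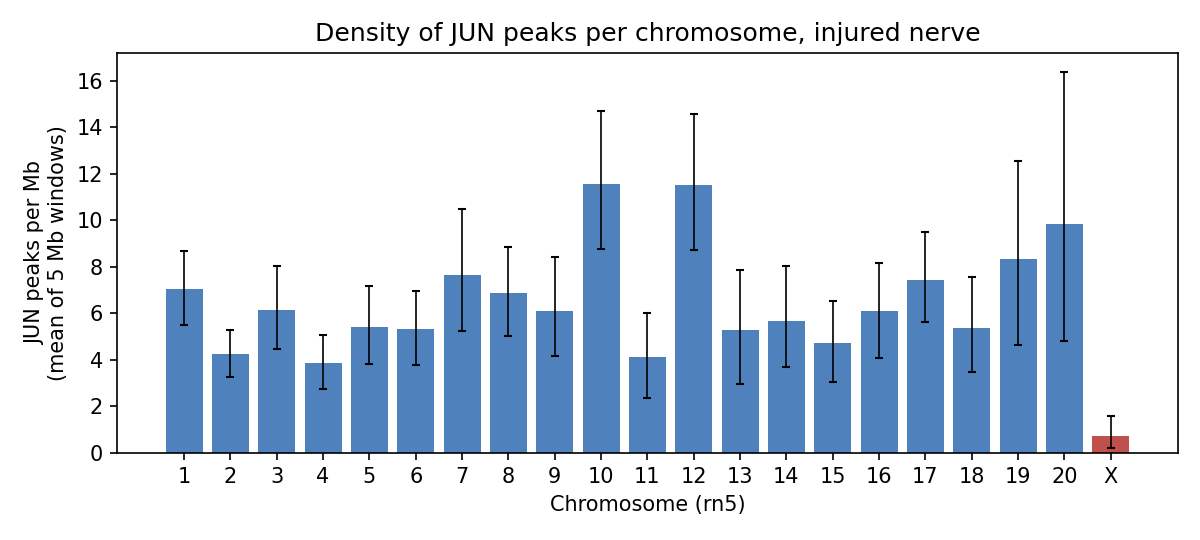
Mean density of JUN peaks per chromosome (peaks per Mb, mean of 5 Mb windows) in injured sciatic nerve, with 95% bootstrap intervals over windows. Chromosomes 10 and 12 stand at 11.6 and 11.5 peaks per Mb, and X, drawn in red, at 0.707.

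X carried 107 peaks, or 0.629% of the peaks on placed chromosomes, while it made up 5.23% of the length up to the last peak. At the autosomal density of 6.20 peaks per Mb, 933 peaks would lie on X. The observed density of 0.710 peaks per Mb was 8.72-fold below that of the autosomes together. It was 5.44-fold below that of chromosome 4, the sparsest autosome when its 67.4 Mb stretch without a peak is counted. The mean over 30 X windows of 5 Mb was 0.707 peaks per Mb (95% bootstrap interval 0.213 to 1.55), against 6.13 over 536 autosomal windows. X minus autosomes was -5.42 peaks per Mb (95% bootstrap interval -6.19 to -4.45; permutation test, 2-sided, p = 1e-05, the smallest that 100000 permutations can give). The rats were male and carry a single X.

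The peaks of X were concentrated in 1 block. Between positions 114775375 and 116358765, a stretch of 1.58 Mb held 67 peaks, which is 62.6% of all X peaks in 1.05% of the X length. The density in this block was 42.3 peaks per Mb. No peak lay in the 7.38 Mb before the block or in the 16.7 Mb after it. Outside the block, X had 40 peaks at 0.268 peaks per Mb, which is 23.1-fold below the autosomal density. The next largest run of peaks on X without a gap over 500 kb held 4 peaks.

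**Figure D2:**
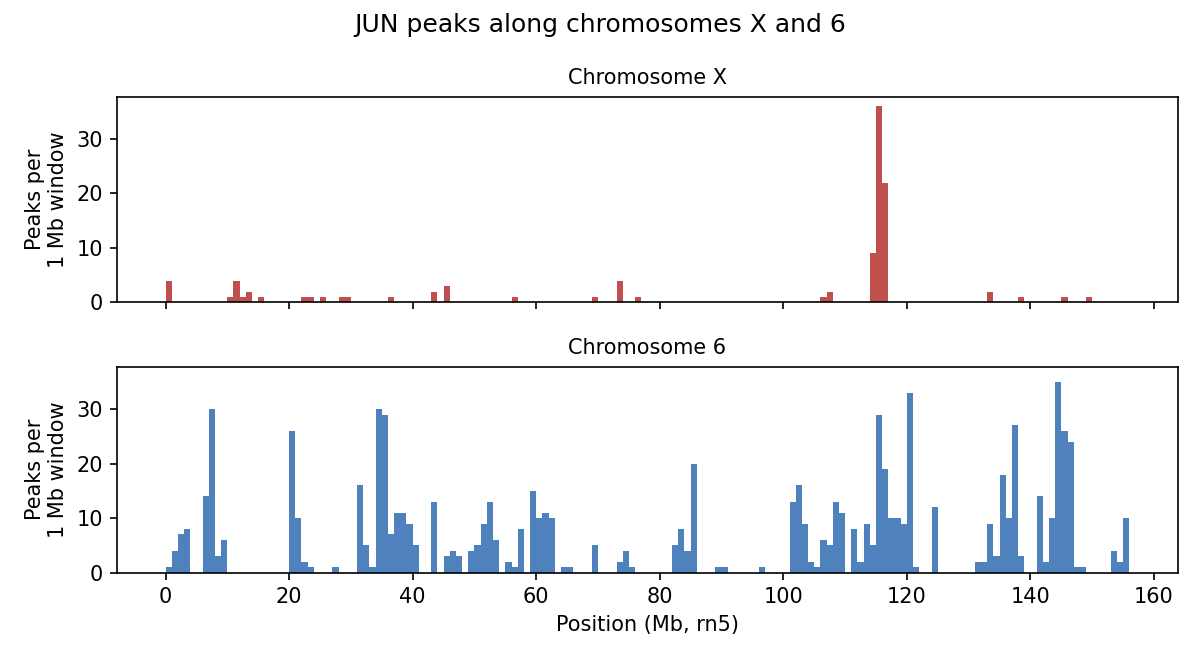
JUN peaks per 1 Mb window along X and along chromosome 6, an autosome of similar length (position in Mb, rn5). X peaks sit mostly in 1 block of 67 peaks near 115 Mb, whereas the 846 peaks of chromosome 6 are spread over many regions.

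Along the chromosomes, JUN peaks were unevenly spread. Of 2868 windows of 1 Mb, 1036 held no peak (36.1%), and the median was 2 peaks per window. A set of 328 windows, 11.4% of all, contained 50% of the peaks. The densest window, at 120 to 121 Mb of chromosome 7, held 73 peaks. It was followed by 7 to 8 Mb of chromosome 20 with 62 peaks, 79 to 80 Mb of chromosome 14 with 59, 11 to 12 Mb of chromosome 7 with 56 and 57 to 58 Mb of chromosome 13 with 54. Chromosome 7 also held 51 peaks at 12 to 13 Mb, next to its second dense window.

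At the other extreme, 16 stretches of at least 10 Mb on 8 chromosomes contained no peak. The longest covered 67.4 Mb of chromosome 4, between positions 67327149 and 134726691. The first 31.0 Mb of chromosome 13 and the first 13.3 Mb of chromosome 11 were also free of peaks. On X, the longest such stretch was 29.2 Mb, and on chromosome 2 it was 20.2 Mb. These are stretches where no peak was listed, and whether peaks could have been called there was not tested. They count among the empty windows and in the chromosome densities above.

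Most JUN peaks had a close neighbour. The median gap between neighbouring peaks was 15.3 kb, with quartiles of 1.57 and 87.7 kb, and 3408 of 16993 neighbouring pairs (20.1%) were less than 1 kb apart. With neighbours joined up to the stitching distance for enhancer clusters, 11383 peaks (66.9%) fell into 3340 groups of at least 2 peaks. The other 5631 peaks (33.1%) stood alone. There were 596 groups of at least 5 peaks, which held 4490 peaks or 26.4% of those placed. Groups of at least 10 peaks numbered 106, had a median length of 34.5 kb and occurred on all 21 chromosomes with peaks. Chromosomes 1 and 10 had the most of these, 13 and 12. X had 1, a group of 18 peaks within the block described above, so X is among the 21 only through that block.

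This grouping exceeded that of peaks placed at random within their own 1 Mb windows. The random placements put 33.2% ± 0.412 (SD, 1000 placements) of peaks into groups, so the observed share of 66.9% was 2.01-fold higher (permutation test by random placement, 2-sided, p = 0.002, the smallest these placements can give). They gave 56.4 ± 6.40 groups of at least 5 peaks, against 596 observed, and at most 5 groups of at least 10 peaks, against 106 observed. Both differences had the same p of 0.002. The size of the excess depended on the placement window. With peaks kept within 250 kb, the placements gave 213 ± 10.5 groups of at least 5 peaks and 16.9 ± 3.26 of at least 10 (SD), which the observed numbers exceeded 2.80-fold and 6.26-fold. With peaks kept within 100 kb, they gave 368 ± 11.9 and 59.2 ± 5.10 such groups, and the excess was 1.62-fold and 1.79-fold, and 1.26-fold for the share in groups (2-sided permutation p = 0.002 in each).

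Pairs of peaks were in excess at short distances. Between 0.3 and 1 kb, 2685 pairs of peak centres were found against 190 ± 13.6 (SD) in the random placements, a 14.1-fold excess. The excess was 8.09-fold from 1 to 2 kb, 4.75-fold from 2 to 5 kb, 3.54-fold from 5 to 10 kb, 2.10-fold from 10 to 50 kb and 1.14-fold from 50 to 200 kb. From 200 to 1000 kb, the ratio was 0.863; because the placements keep the number of peaks per window, an excess of close pairs lowers the number of distant ones. Each of the 7 distance classes differed from the placements (2-sided permutation test, Benjamini-Hochberg adjusted p = 0.002).

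**Figure D3:**
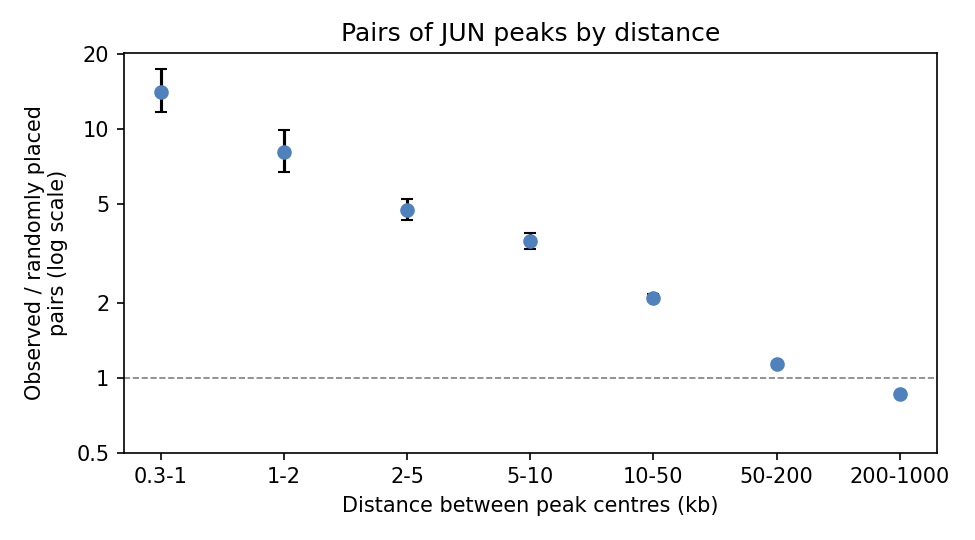
Ratio of observed to randomly placed pairs of JUN peaks by distance between centres (kb; log scale for the ratio). Points are ratios to the mean of 1000 placements within 1 Mb windows and bars the range over the placements; the ratio falls from 14.1 below 1 kb to 1.14 at 50 to 200 kb.

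The largest group lay on chromosome 12 from 38747527 to 38889574 and held 34 peaks over 142 kb, with a median gap of 2.49 kb. The second, on chromosome 17 from 756441 to 816144, held 33 peaks in 59.7 kb with a median gap of 0.878 kb. Groups of 24 peaks were found on chromosome 12 from 13530471 to 13584730 and on chromosome 18 from 78826135 to 78907999. Groups of 23 peaks lay on chromosome 19 from 41701998 to 41772050 and on chromosome 7 from 120384956 to 120454437, within the densest 1 Mb window. Chromosomes 13 and 15 had groups of 22 peaks, from 114500089 to 114546800 and from 28875833 to 28927987. A group of 21 peaks on chromosome 1 from 274490715 to 274527099 was the most closely packed of the 10 largest, at 5.77 peaks per 10 kb, and another group of 21 lay on chromosome 13 from 57595421 to 57656396. The largest group in the 1000 random placements of the whole list within 1 Mb windows had 19 peaks; in a further 1000 placements without X it had 21, as many as the smallest of these 10. Placements within 100 kb windows gave largest groups of 28.4 ± 3.97 peaks (SD), from which the observed 34 did not differ (permutation test by random placement, 2-sided, p = 0.238).

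Runs of peaks in near contact were short. With gaps under 500 bp, 3 runs of 5 peaks were the longest. They lay on chromosome 10 from 55424836 to 55427590 and from 76953083 to 76956031, and on chromosome 17 from 17676396 to 17679227.

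**Figure D4:**
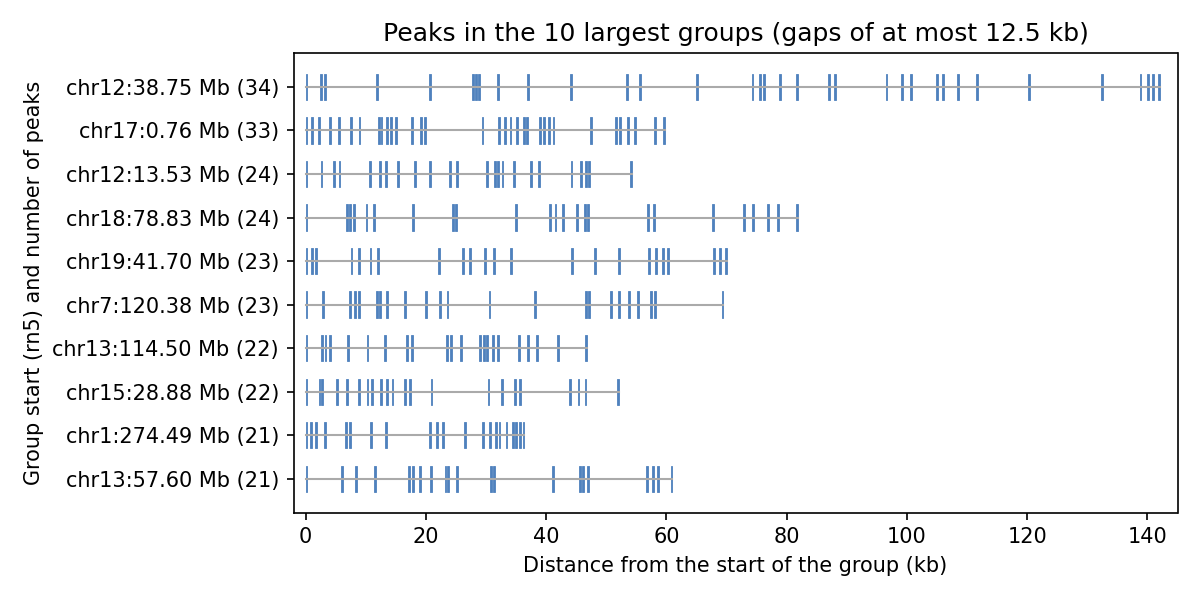
Peaks of the 10 largest groups, drawn to scale as 0.3 kb bars along the distance from the start of each group (kb); labels give the group's start on rn5 and its number of peaks. The group on chromosome 12 spans 142 kb with 34 peaks, and the group on chromosome 1 packs 21 peaks into 36.4 kb.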

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

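Of 28 other settings listed before the data were examined, 3 could be computed; the other 25 need a peak score, an rn5 gene annotation or an rn5 sequence and were not run. The settings used here other than the gaps of 5 and 25 kb and the 500 bp join for the number of peaks were chosen after seeing the data. Joining peaks closer than 500 bp left 15120 of 17017 peaks. The share of peaks in groups stayed above that of random placement in each of the 9 alternatives computed, by 1.26-fold to 4.35-fold (2-sided permutation p = 0.002 in each), and the density on X stayed below that of the autosomes in each of 4 alternatives, with a ratio of 0.0433 without the block of X and 0.112 to 0.116 in the others. Numbers of groups depended on their definition. Drawing 50% of the peaks at random gave 1561 groups of at least 2 peaks, against 3340; the others gave 2403 to 3327. At the 25 kb gap, the number of groups of at least 2 peaks, 3183, was 0.983 times that of random placement (2-sided permutation p = 0.09), as the mean of the placements rose from 2404 at the stitching distance to 3237. Groups of at least 5 peaks, 596 at the stitching distance, rose to 821 with gaps of 25 kb and fell to 367 with gaps of 5 kb. They numbered 408 and 269 after joining peaks closer than 500 bp and 1 kb, and 139 with 50% of the peaks. Groups of at least 10 peaks, 106 at the stitching distance, were 31 with gaps of 5 kb, 210 with gaps of 25 kb, 65 and 31 after joining peaks closer than 500 bp and 1 kb, and 7 with 50% of the peaks. How these counts would move with the authors' threshold was not tested, as the list has no score. No paired analysis was possible because the list has no column per replicate, and no replicate could be left out for the same reason. Depth was unknown, so a region without a peak is one where no peak was listed, not one shown to lack JUN.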

Other observations

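The tests on X and its block, the random placements with their windows and joins, the recurring spacings and the adjacent windows were chosen after the peak list was seen. Adjacent 1 Mb windows of the autosomes held similar numbers of peaks, with Spearman's rho 0.496 and Pearson's r 0.371 over 2698 adjacent pairs (permutation p = 0.001 for rho, the smallest that 1000 shuffles of windows within chromosomes can give). Windows are not independent replicates. The dense windows of chromosome 7, at 11 to 12 and 12 to 13 Mb, and of chromosome 1, at 56 to 57 and 57 to 58 Mb with 46 and 44 peaks, are examples of neighbours that are both among the densest of the list.

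For the grouping of peaks, 3 technical explanations were tested. The share of peaks in groups was 15.4% for placement over whole chromosomes and 33.2% for placement within 1 Mb windows, and the observed 66.9% was 2.01-fold above the latter, which argues against regional density at the megabase scale as the whole cause. After peaks closer than 1 kb were joined, the excess was 2.07-fold. This argues against splitting of 1 enriched region into several fixed-width intervals as the whole cause, for pieces less than 1 kb apart. The join lowered groups of at least 5 peaks from 596 to 269 and groups of at least 10 from 106 to 31. How many of the joined peaks were splits is unknown, so splitting may account for part of the large groups. Splitting into pieces further apart was not tested. Repeated segments of the build are argued against only for groups of at least 4 peaks and for copies that keep their spacings. Of 3070 runs of 4 peaks inside groups, 0 had their 3 spacings recur elsewhere within 2 bp. This allows a share of up to 0.0977% by 3 counts of the total and 0.120% by the exact 95% interval. Runs of the same group share peaks, so these limits may be too low. Groups of 2 or 3 peaks could not enter the test. Copies whose called peaks shifted by more than 2 bp, or lost a peak, would not be seen. Placement within 250 kb and 100 kb windows left a smaller excess, 1.48-fold and 1.26-fold, but the peak counts of such windows are partly made up by the groups themselves, so these values do not show how much of the grouping regional density accounts for. Density of any origin below 100 kb was not tested, and a biological reading, that groups mark clustered JUN-bound enhancers, remains an untested hypothesis.

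The low number of peaks on X may be technical or biological. A few long stretches of X without usable sequence are argued against as the whole cause: among 1 Mb windows that held a peak, the median was 1 peak on X (27 windows) and 6 on the autosomes (1805 windows), a ratio of 0.167 (95% bootstrap interval 0.167 to 0.333). The single X of male rats would lower the signal all along X, but the ratio of densities, 0.115, cannot show how many peaks a lower signal costs at the authors' threshold. Read coverage of X in the ChIP and input libraries was not analysed here. The design has no group that would test a biological explanation.

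The block of 67 peaks on X stands out against the rest of that chromosome. One candidate explanation is that autosomal sequence was placed on X in rn5, and another is that X holds a dense region of the kind autosomes also hold; these cannot be told apart without the sequence of the block or a later assembly. The block had more peaks than 99.6% of the 20277 autosomal windows of its length that held a peak, but fewer than the highest of them, 97, so its density is possible for an autosome. These windows were taken in steps of 100 kb and overlap, so they are not separate regions. The block was cut at its own first and last peak and the windows were not, which favours a high rank of the block. Of 45 autosomal runs with at least 67 peaks and no gap over 500 kb, 1 had at least 5 Mb without a peak on both sides (chromosome 3 from 86004373 to 90360955, with 71 peaks). It was also the only 1 among all 258 autosomal runs with at least 20 peaks. These counts do not bear on the second explanation, because X outside the block has 0.268 peaks per Mb against 6.20 on the autosomes, so a dense region native to X would tend to be isolated as well.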
